A study of Homo sapiens with 4 samples.

How the data were processed

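The series holds 4 single-cell RNA libraries of human peripheral blood mononuclear cells (PBMC), made with the 10x Genomics 5' version 2 chemistry. Per the labels, the cells came from a healthy control (HC) or a shrimp-allergic (SA) donor group and received 0 or 1 ug/mL of tropomyosin, the muscle protein that is the main shrimp allergen. That gives 4 groups with 1 library each, so there were no replicates. The labels do not say whether the library with and the library without tropomyosin of a donor group came from the same person. Donor and allergy can therefore not be told apart in any comparison of SA with HC.

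The values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, deposited as filtered matrices of 36601 genes. The values in these matrices are whole numbers. The submitters' processing notes name Cell Ranger 6.1.2, the genome build GRCh38 and Seurat 4.3.0, without saying what each was used for, and the gene annotation release is not stated. Only the deposited counts were used here, with gene symbols as the matrices give them.

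Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs. Doublet scores came from Scrublet as implemented in scanpy 1.11.5. Its automatic threshold called almost no doublets, so the highest-scoring cells of each library were removed at a rate of 0.8% per 1000 cells, a rule chosen after seeing the data. Counts were scaled to 10000 per cell and log-transformed, and the 4 libraries were clustered together with Leiden at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) on 2000 variable genes, 30 principal components and 15 neighbours. Variable segments of the T cell receptor and immunoglobulin genes, sex-linked, mitochondrial and ribosomal protein genes were not used for clustering. No correction for donor or library was made. T and NK clusters were then clustered a second time on their own variable genes, with the T cell receptor delta and gamma genes let back in. Gamma delta T-like, MAIT-like and Treg-like clusters were named by marker genes listed beforehand among their leading genes. A gamma delta name also needed a delta V UMI in most cells. B-like and monocyte-like clusters needed a leading marker gene and given shares of cells with UMIs of CD79A, or of LYZ and CD14. CD4 T-like, CD8 T-like and NK-like clusters were named by shares of cells with UMIs of CD4, CD8B, KLRF1 or CD3D. No other class could have more markers among their leading genes, but their own could be absent. Names end in "-like" because no protein was measured. Clusters that met no marker rule were left unnamed.

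For each library and class, UMIs were summed and expressed as counts per 1000000 UMIs of that class (CPM). Each CPM has an exact Poisson 95% interval, each log2 ratio of CPM an exact conditional binomial 95% interval, and each share of cells an exact Clopper-Pearson 95% interval. Each median of a gene list has a 95% interval from 500 Poisson draws of its members. All of these intervals cover counting error only, and say nothing about differences between donors or wells. With 1 library per group, no test was run and no p-value is given, since cells of 1 library are not replicates of a group. A count of 0 was set to the floor of 3 counts and its ratio is given as a bound ("at least"). This bound rests on the floor and is not a 95% limit, which can lie lower. Intervals in brackets are on the scale of the value before them.

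The contrasts were tropomyosin against no tropomyosin within HC and within SA, and SA against HC without and with tropomyosin. A class needed at least 20 cells in each library of a contrast. There were 26 gene lists fixed beforehand. A list was summarised by the median log2 ratio of its measured members (at least 10 UMIs over both libraries), the number of members at least 1.5-fold higher or lower, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. On simulated Poisson counts, which leave out single cells very rich in a gene, lists with no change had percentiles from 0.31 to 97.5. The percentile is therefore descriptive. Lists were discussed where the median and the number of changed members stood out, a choice made after seeing their values.

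Genes were named by a rule fixed beforehand: for each contrast, the 6 genes with the highest and the 6 with the lowest ratio in gamma delta T-like cells, and the 2 highest and 2 lowest in each other class. They needed at least 50 UMIs (30 in gamma delta T-like cells) in 1 of both libraries, intervals that do not overlap and a 1.5-fold ratio. Up to 4 members of each list discussed were added, and IL10, TGFB1, IL4, IL5, IL13, IFNG, TNF, IL17A and AREG in gamma delta T-like cells. IL1B, CXCL8, TNF, IL10 and IL1RN in monocyte-like cells, the detection shares of delta V genes and the genes in the closing section's opposite responses were added after their values were seen. Genes whose level is known to follow inherited variants, or whose reads are shared with near-identical copies, were left out of the text after values were seen (16 entries). Genes that lead a sub-cluster of a class are not named as results in that class, apart from members of the interferon list in CD4 T-like cells and, in monocyte-like cells, S100A9 and members of the inflammatory list (CXCL8, IL1B, CXCL5 and CXCL1 are among the leading genes of that cluster). Genes with most UMIs of a library in 1 cell are named as such. The marker genes, gene lists, filters and the first set of alternatives were chosen before the data were examined.

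The intervals and the recovery of known changes were tested on simulated data, with 200 genes changed in Poisson counts drawn at the depth of these libraries. The intervals assume such counts, so the coverage given next checks the computation and not the data. Single cells very rich in a gene were not simulated, so recovery in the data can be lower. In gamma delta T-like cells of HC the interval held the true ratio for 96.8% of 6949 genes. There the interval-and-fold rule recovered 52.7% of 93 genes changed 2-fold and 88.2% of 85 genes changed 4-fold. In CD4 T-like cells, which are far more numerous, it recovered 86.9% of 2-fold and 97.0% of 4-fold changes.

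Alternatives planned at the start were a mitochondrial limit of 5% or 20%, doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, per-cell gates for gamma delta T cells (also with every cell thinned to 2000 UMIs), scaling by edgeR TMM (4.0.16) or DESeq2 median-of-ratios factors (1.42.0), CPM without mitochondrial, ribosomal protein and immunoglobulin genes, and other UMI minimums. The first gate asked for CD3 and TRDC with no TRAC, TRBC1 or TRBC2 UMI and the second, called the delta V gate below, for CD3 and TRDV1, TRDV2 or TRDV3. Added after seeing the data were leaving out the 10% of cells richest in a list, thinning cells in the same way for list medians and leaving out the top cell of a gene. The delta V gate for expression and leaving out sub-clusters led by heat shock or interferon-stimulated genes were added then too. The heat shock sub-clusters held only unnamed T and NK cells, so leaving them out changed no class with expression ratios and tested nothing there. TMM moved all log2 ratios of a contrast by more than 0.1 in 5 places. In SA against HC these shifts were -0.26 (with tropomyosin) and -0.14 (without) in CD8 T-like cells, -0.20 with tropomyosin in CD4 T-like cells and -0.16 with tropomyosin in B-like cells. The tropomyosin contrast of HC monocyte-like cells shifted by 0.11. Median-of-ratios factors gave -0.25, -0.14, -0.19, -0.14 and 0.10 in the same order.

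Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and in R 4.3.3.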

Results

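RNA was counted in single PBMC of 4 libraries, 1 per group: HC without tropomyosin, HC with 1 ug/mL tropomyosin, SA without and SA with 1 ug/mL. In that order, which is kept below, the libraries held 4545, 5487, 5393 and 3804 barcodes with 19979037, 22616111, 22466190 and 17061006 UMIs. The median barcode had 3917, 3541, 3418 and 3794 UMIs and 1435, 1317, 1373 and 1510 genes, with 3.41%, 3.51%, 2.68% and 2.88% mitochondrial UMIs. After filtering, 4369, 5236, 5155 and 3682 cells were used. There were no replicates, so every comparison below is between single libraries, and differences are described by size with counting intervals only.

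The question for the cell classes was whether donor groups or tropomyosin went with another make-up of the cells, above all of gamma delta T cells, which the series title names. The shares are those of cells recovered in the libraries and need not be those in blood. CD4 T-like cells were the largest class, with 37.5% [36.1, 39.0], 37.3% [36.0, 38.6], 38.7% [37.4, 40.1] and 38.9% [37.3, 40.5] of cells. CD8 T-like cells were 24.3% [23.1, 25.6], 22.6% [21.4, 23.7], 24.4% [23.2, 25.6] and 27.0% [25.5, 28.4]. NK-like cells, innate killers, were more frequent in SA: 8.07% [7.34, 8.85] and 7.74% [6.90, 8.65], against 4.92% [4.3, 5.60] and 5.44% [4.84, 6.09] in HC. B-like cells, led by naive B cell genes such as TCL1A and IGHM, were less frequent in SA with tropomyosin, at 6.17% [5.41, 6.99] against 9.78% [8.99, 10.6] in HC. Without it the intervals overlapped, at 6.98% [6.30, 7.71] and 8.10% [7.31, 8.95] (6.07% [5.42, 6.78] and 6.63% [5.87, 7.47] with a 5% mitochondrial limit). With Leiden resolution 0.5, which joined them to the class-switched B cells left unnamed here, they were 13.6%, 14.7%, 9.0% and 8.39%, and with HC without tropomyosin clustered on its own 13.8%. Monocyte-like cells were 2.01% [1.62, 2.48], 1.83% [1.49, 2.23], 3.82% [3.31, 4.38] and 2.55% [2.07, 3.12]. Treg-like cells were 2.54%, 2.27%, 3.14% and 3.10%. MAIT-like cells, innate-like T cells, were 2.72%, 2.29%, 2.29% and 2.09%, and 4.76%, 5.02%, 4.91% and 4.81% at resolution 0.5, where they merged with gamma delta T-like cells. With SA with tropomyosin clustered on its own they were 4.94% there, and with a 5% mitochondrial limit 1.54% in HC with tropomyosin. T or NK cells left unnamed made up 10.1%, 10.3%, 7.43% and 7.25%.

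**Figure D1:**
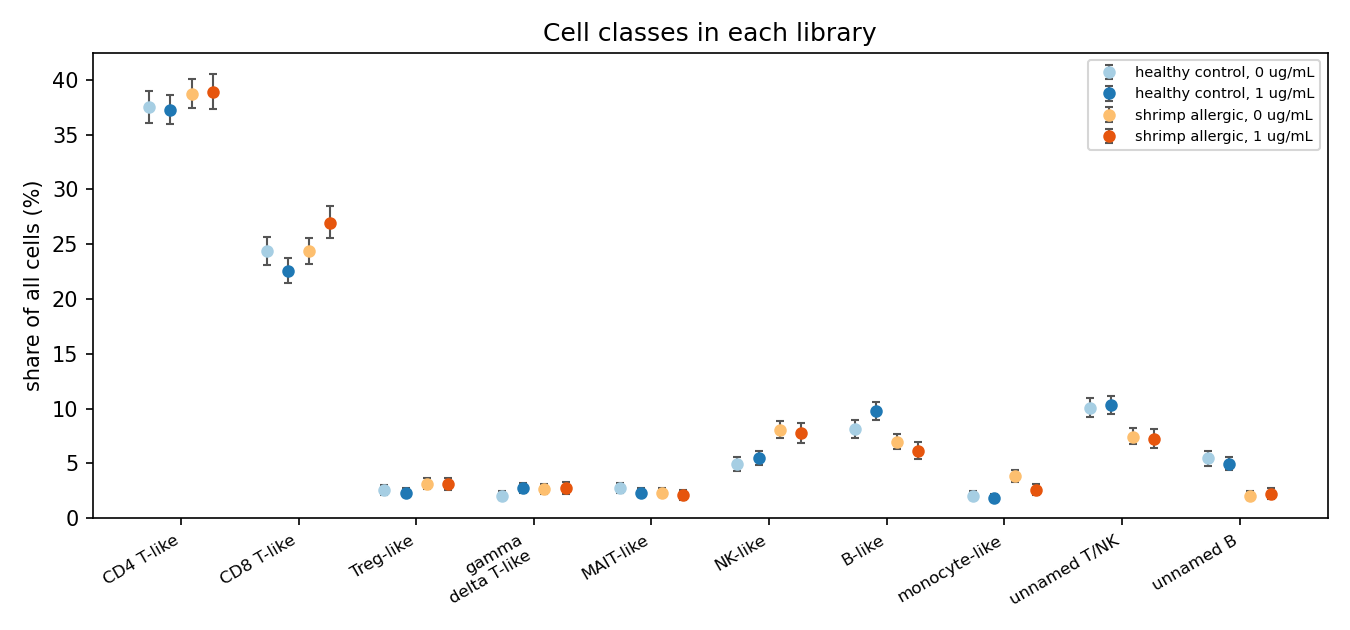
Share of cells (%) of each named class in the 4 libraries, with exact 95% binomial intervals as error bars. NK-like cells are higher in both SA libraries (8.07% and 7.74%) than in both HC libraries (4.92% and 5.44%).

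Gamma delta T-like cells were the sub-cluster led by TRDV2 and TRGV9, the receptor pair of the main gamma delta T cells of blood. They were 2.57% [2.07, 3.16], 3.50% [2.96, 4.11], 3.33% [2.80, 3.93] and 3.35% [2.74, 4.06] of T cells, and 2.04%, 2.71%, 2.62% and 2.72% of all cells (89, 142, 135 and 100 cells). The intervals of SA and HC overlapped both without and with tropomyosin. With a 5% mitochondrial limit they did not overlap without it, at 3.37% [2.82, 3.99] of T cells in SA and 2.09% [1.61, 2.65] in HC. A delta V gene was found in 91.0%, 89.4%, 94.8% and 90.0% of them, at median depths of 2848, 2617, 2818 and 3391 UMIs, against 0 of 354, 2 of 512, 2 of 360 and 0 of 227 B-like cells, which should lack it (3140, 2810, 2706 and 3032 UMIs). Delta V genes helped to draw and name this sub-cluster, so these shares describe it and are no independent support for its name. TRDC was found in 45.5% of its cells over the 4 libraries together. The sub-clusters that TRDV1 helped to lead were left unnamed, and 11.6%, 13.5%, 37.9% and 38.6% of the unnamed T and NK cells had a delta V UMI. So did 32, 32, 32 and 19 CD4 T-like and 19, 22, 32 and 27 CD8 T-like cells. The delta V gate takes in all of these that had a CD3 UMI, and gave 5.37%, 6.34%, 8.54% and 8.25% of T cells, or 4.34%, 4.91%, 6.85% and 6.65% with every cell thinned to 2000 UMIs. By that gate SA was above HC. The gate on TRDC without alpha or beta constant genes was almost empty, at 0.173%, 0.173%, 0.222% and 0.0335% of T cells.

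The first stimulation contrast asks what tropomyosin went with in cells of a non-allergic donor group. Interferon-stimulated genes, the antiviral program that type I interferon turns on, were higher in HC cells with tropomyosin in all 6 classes examined. In gamma delta T-like cells the list's median log2 ratio was 1.26 [0.97, 1.69], with 16 of 17 members at least 1.5-fold higher: IFI6 was at 2.12 [1.09, 3.32] (1.17 with a 5% mitochondrial limit), OAS1 at 1.98 [0.19, 4.40] (17 against 3 UMIs, and 2.59 with that limit), RSAD2 at 1.94 [-0.26, 5.15] (11 against 2, and 1.16 with the delta V gate) and IFI44L, with 21 UMIs against 0, at least 4.88-fold higher. NK-like cells had a median of 1.14 [0.76, 1.29], with OAS1 at 2.05 [1.11, 3.13], IFI44L at 2.03 [1.05, 3.17] and IFIT3 at 1.60 [0.77, 2.52]. Monocyte-like cells had 1.16 [0.99, 1.35] (2.02 without the 10% of cells richest in the list), with IFIT2 at 2.65 [2.01, 3.35] and MX1 at 1.72 [1.43, 2.01]. B-like cells had 0.79 [0.62, 0.99] (0.39 without those cells), with IFI44 at 2.29 [0.93, 4.01]. CD8 T-like cells had 0.30 [0.19, 0.42] (0.11 without them) and IFI6 at 0.91 [0.60, 1.23]. CD4 T-like cells had 0.31 [0.24, 0.44] (0.13 without them), with IFIT2 at 1.54 [1.0, 2.12] (0.78 without its top cells), IFIT1 at 1.48 [0.89, 2.11], OASL at 1.28 [0.74, 1.85] and IFIT3 at 1.16 [0.67, 1.66]. The sub-cluster led by IFIT3 and IFIT1 held 111 of 1952 of these cells with and 44 of 1639 without tropomyosin. None of its leading genes was a CD4 T cell marker, and it was named by CD4 UMIs in 27.0% and CD8B UMIs in 9.5% of its cells. Without that sub-cluster the list's median was 0.0495, but the listed genes helped to draw it, so a fall was set in advance.

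**Figure D2:**
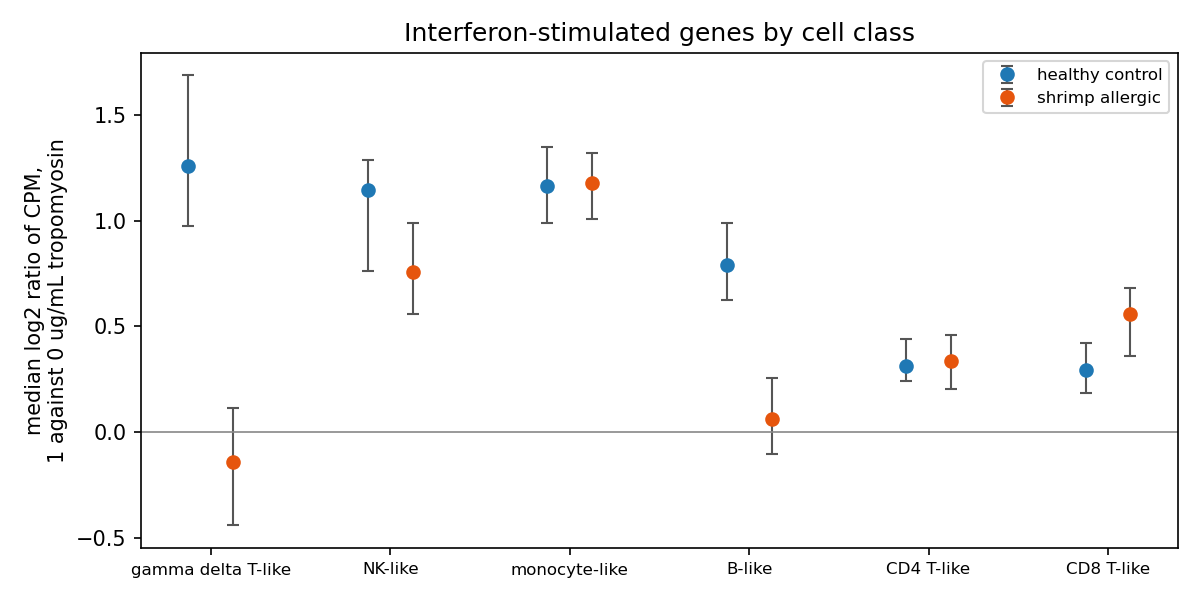
Median log2 ratio of CPM (with tropomyosin over without) of the interferon-stimulated genes in 6 classes, for HC and SA, with 95% counting intervals. HC gamma delta T-like cells sit at 1.26 and SA gamma delta T-like cells at -0.14, while both monocyte-like medians lie near 1.16 and 1.18.

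In HC gamma delta T-like cells the genes with high ratios with tropomyosin included IFI6, NFKB1, a subunit of the inflammatory regulator NF-kB (1.90 [0.62, 3.44], 1.01 with doublets kept, 0.59 by the gate), LGALS1, a galectin that dampens T cells (1.86 [0.87, 3.0], 0.94 by the gate), the ubiquitin-like protein ISG15 (1.61 [0.81, 2.49]) and DNPH1 (1.57 [0.64, 2.61], 0.33 by the gate). The lowest were TNFRSF1B, a receptor for TNF (-1.27 [-2.17, -0.41]), G3BP1 (-1.14 [-1.95, -0.36]), RPN2 (-0.85 [-1.43, -0.27]), the chaperone HSPA5 (-0.81 [-1.31, -0.31], -0.17 by the gate), EZR (-0.69 [-1.14, -0.24], -0.12 by the gate) and the activating receptor KLRK1 (-0.64 [-1.06, -0.22]). NF-kB targets had a median of 0.56 [0.27, 1.11], with 6 of 12 members higher, among them BIRC3 at 1.97 [0.57, 3.70] (0.97 by the gate) and NFKB2 at 1.33 [0.42, 2.34] (0.66 by the gate). Interferon gamma-induced genes had 0.51 [0.23, 0.92], with GBP5 at 0.81 [0.19, 1.46] and SOCS1 at 0.90 [0.01, 1.86].

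HC monocyte-like cells with tropomyosin had more inflammatory cytokine RNA. The list's median was 1.41 [1.08, 1.63], with 16 of 20 members higher (1.75 with cells thinned). IL6, a fever and acute-phase cytokine, was at 198 against 18.5 CPM (3.42 [2.87, 4.02]), and IL1B at 3319 against 1077 CPM (1.62 [1.55, 1.70]). The neutrophil attractant CXCL8 was at 4406 against 2603 CPM and CCL4, also a leading gene of NK-like cells, at a ratio of 2.63 [2.53, 2.73]. Cytotoxic genes, transcripts of T and NK cells, were higher in these cells as well (median 0.95, and 0.24 over members with at least 50 UMIs). CCL20 was at 4.23 [2.96, 5.88] on 106 against 5 UMIs, 60% of those 5 in 1 cell (5.17 without the top cells). Metallothioneins, which bind zinc, were higher with a median of 0.79 [0.66, 1.01] in 6 of 7 members, and SOD2, an NF-kB target, was at 1.07 [1.01, 1.12]. SDS was at -4.21 [-5.69, -3.03] on 6 against 98 UMIs, 66.7% of those 6 in 1 cell (-5.56 without the top cells). IL22 and MMP1 in these cells, and IL2 (1933 UMIs), IL21, CCL1 and LTA in NK-like cells, did not meet the naming rule without the top cell of each library.

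Other genes named in HC were TMEM251 (1.45 [0.76, 2.20]), MRE11 (-1.24 [-1.91, -0.60]) and TSC22D2 (-1.07 [-1.74, -0.42]) in B-like cells, MARCH2 (-1.01 [-1.67, -0.37], -1.60 with a 5% mitochondrial limit) and TMOD2 (-1.01 [-1.69, -0.35]) in CD8 T-like cells, and ZSCAN5A (-1.0 [-1.68, -0.34]) in CD4 T-like cells. HSPA1A in B-like cells was at 1.42 [0.57, 2.35], and at -0.04 without its top cell.

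The second stimulation contrast asks the same of the allergic donor group, whose cells would be the ones primed to the allergen. Interferon-stimulated genes were again higher in monocyte-like cells, with a median of 1.18 [1.01, 1.32] (1.80 with cells thinned). IFI27 was at 5.07 [4.12, 6.22] (213 against 9 UMIs, these 9 in 1 cell, and at least 6.32 without the top cells), IFIT2 at 3.75 [2.85, 4.80], IFIT1 at 3.63 [2.68, 4.74] and IFIT3 at 2.83 [2.24, 3.47]. NK-like cells had a median of 0.76 [0.56, 0.99] (0.52 without the richest 10%), with IFI44L at 1.92 [1.22, 2.66] and XAF1 at 1.23 [0.78, 1.70]. CD8 T-like cells had 0.56 [0.36, 0.68] (0.21 without the richest 10%), with IFIT3 at 1.78 [0.94, 2.70], and CD4 T-like cells 0.34 [0.20, 0.46], with IFIT3 at 1.78 [0.92, 2.70] and OAS3 at 1.16 [0.53, 1.81]. SA gamma delta T-like cells had a median of -0.14 [-0.44, 0.11], with 1 of 17 members higher and 3 lower (0.22 with the delta V gate), and SA B-like cells one of 0.06 [-0.10, 0.26].

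SA gamma delta T-like cells also had no detectable shift of NF-kB targets (0.01) or interferon gamma-induced genes (-0.17 [-0.38, 0.11]). Among the latter, PSMB9, a proteasome subunit for antigen processing, was at -0.47 [-0.84, -0.11], and at 0.03 with the delta V gate. The highest ratios were those of OSBPL9, a lipid carrier (1.97 [0.86, 3.22], 0.39 by the gate, which is the second value for the genes that follow), ESD (1.60 [0.60, 2.69], 0.85), FAM200B (1.35 [0.47, 2.30], 0.65), BCLAF1 (1.23 [0.60, 1.88], 0.26), VPS51 (1.12 [0.41, 1.87], 0.71) and HELZ (1.12 [0.40, 1.88], 0.70). UMAD1 (-1.92 [-3.35, -0.70], -0.47), CASK (-1.45 [-2.64, -0.39], -0.43, and -0.86 with doublets kept), MAPKAPK2, a kinase that stabilises cytokine RNA (-1.26 [-2.00, -0.56], -0.32), NSMCE3 (-1.17 [-1.99, -0.40], -0.58), MORC3 (-1.16 [-2.00, -0.36], -0.35) and DAZAP1 (-1.14 [-2.02, -0.32], -0.47) were lowest.

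In SA monocyte-like cells the inflammatory list had a median of 1.25 [0.73, 1.49], with 14 of 21 members higher (1.53 with cells thinned). IL1B was at 1494 against 567 CPM (1.40 [1.31, 1.49]), CCL20, which attracts CCR6-bearing lymphocytes, at 79.6 against 5.49 CPM (3.86 [3.11, 4.70], 3.20 without its top cells), TNF at 2.24 [1.87, 2.62] and CCL4 at 2.95 [2.88, 3.02]. IL6 was at 12.2 against 1.03 CPM, on 25 against 3 UMIs (3.57 [1.85, 5.94], 2.83 without its top cells). NF-kB targets were higher in 13 of 16 members, with a median of 0.82, led by TRAF1 (1.78 [1.45, 2.13]) and ZC3H12A (1.71 [1.30, 2.14]). The tryptophan-degrading enzyme IDO1 was at 2.73 [2.28, 3.20]. Transcripts of T and NK cells were lower in these cells: cytotoxic genes had a median of -0.75, checkpoint genes -0.80 and naive T cell genes -0.34. Genes that mark monocytes were also lower (-0.30). Metallothioneins were lower in 7 of 7 members, with a median of -2.04 [-2.32, -1.81] (-2.69 with cells thinned) and MT1M at -4.63 [-6.10, -3.49]. The suppressive cytokine IL10 was at 9.77 against 23.7 CPM (-1.28 [-2.08, -0.54]), whereas in HC it was at 23.7 against 14.0 CPM (0.76 [-0.02, 1.57]). IL1RN, which blocks the IL-1 receptor, was higher in both, at 0.82 [0.60, 1.04] in HC and 0.77 [0.58, 0.95] in SA. CXCL10 was at 5.42 [4.52, 6.50] and FABP4 at -5.93 [-6.84, -5.15], each with most UMIs of either library in 1 cell, and at 5.17 and -6.18 without these cells. CXCL11 in these cells, and IL3 and IL2 in NK-like cells, rested on 1 cell each.

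**Figure D3:**
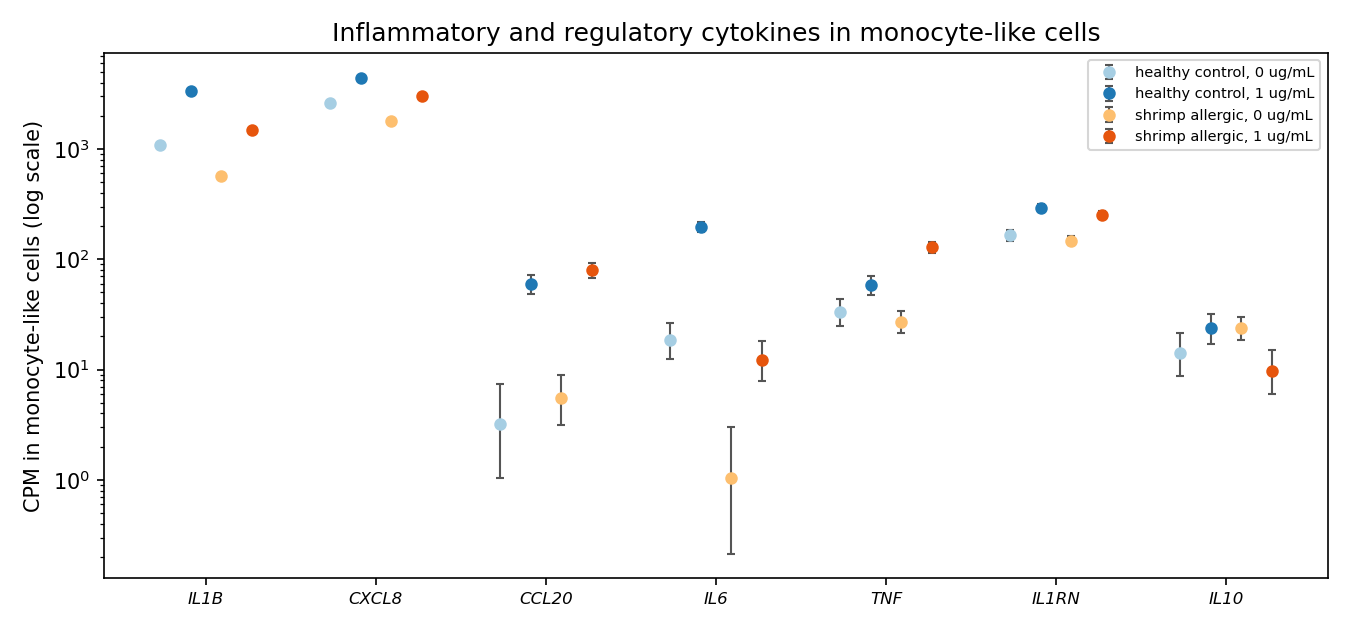
Level (CPM, log axis) of inflammatory and regulatory cytokine RNA in monocyte-like cells of the 4 libraries, with exact Poisson 95% intervals. IL1B and IL6 are higher with tropomyosin in both donor groups, and IL6 is lower in SA (1.03 and 12.2 CPM) than in HC (18.5 and 198 CPM).

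In the other SA classes, PPBP, a platelet transcript, was at 2.04 [1.57, 2.54] in CD8 T-like cells, and at -0.37 with a 5% mitochondrial limit. Cytotoxic genes of CD8 T-like cells were at medians of 0.03 in HC and 0.07 in SA, and in SA at -0.0047 with TMM and -0.021 with doublets kept. ZNF594 was at 1.74 [0.96, 2.58] and RRBP1 at -1.08 [-1.68, -0.51] there. CD4 T-like cells had FAM89B at 1.11 [0.75, 1.48] and CEBPD at -1.45 [-2.33, -0.65]. B-like cells had the interferon-induced GTPase GBP1 at 1.17 [0.60, 1.75], PIGF at -1.45 [-2.45, -0.55] and KDM2B at -1.22 [-2.06, -0.44]. The type 2 list, which holds the classical allergy cytokines, could be read in CD4 T-like cells for 5 members in HC (0.02) and 4 in SA (0.32, and -0.54 when members with 1 UMI were let in). Its members with enough counts were receptors and regulators, such as GATA3 at 0.30 [0.12, 0.47] and IL4R at -0.40 [-0.68, -0.12] in SA.

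SA against HC without tropomyosin asks how the donor groups differed in cells that received no allergen. In CD8 T-like cells the cytotoxic effector list, the killing machinery of T and NK cells, had a median of 1.53 [1.40, 1.69], with 11 of 12 members higher. NKG7 was at 1.88 [1.79, 1.97], GZMB at 1.80 [1.58, 2.02] and KLRD1 at 1.66 [1.31, 2.01]. The sub-cluster led by GZMH and CD8A made up 41.6% of SA and 18.7% of HC CD8 T-like cells, and the one led by LINC02446 and CD8B 48.8% and 69.0%. The median was 1.34 with cells thinned, 1.39 with TMM and 2.28 without the richest 10% of cells. ADTRP at -3.61 [-5.10, -2.41] (-2.62 with doublets kept) and SCGB3A1 at -3.32 [-4.58, -2.27] were lowest. In CD4 T-like cells the cluster led by NOG and TSHZ2 held 829 of 1997 cells in SA and 315 of 1639 in HC, and that led by ADTRP and SOCS3 304 and 750. NOG and FHIT were among the leading genes of both clusters, which were drawn without a donor or library correction. Another mix of CD4 T-like cells can therefore not be told apart from an expression difference between donors or libraries. Interferon gamma-induced genes were lower in CD4 T-like cells of SA, with a median of -0.93 (-0.72 without the richest 10% of cells, -0.61 thinned) and GBP5 at -1.34 [-1.57, -1.11].

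Gamma delta T-like cells of SA had S100B, a calcium-binding protein, at 40 UMIs against 1 (4.78 [2.22, 10.12], 3.75 with doublets kept, at least 3.0, on 35 against 0, without its top cells, 2.16 by the gate), the TGF-beta repressor SKI at 32 against 2 (3.46 [1.49, 6.56], 2.87 with doublets kept, 4.36 without its top cells, 1.26 by the gate), NFKB1 at 2.71 [1.5, 4.21] (1.79 with doublets kept, 1.0 by the gate), NXPH4 at 2.61 [1.83, 3.48], DNPH1 at 2.54 [1.68, 3.54] (0.79 by the gate) and SMURF2, which limits TGF-beta signals, at 2.29 [1.15, 3.68] (1.25 by the gate). The quiescence factor KLF2 was at -2.41 [-3.28, -1.62], at -0.20 by the gate and -1.0 with doublets kept. SYTL3 (-2.04 [-3.18, -1.01], -1.36 by the gate), TNFRSF1B (-1.64 [-2.63, -0.71], -2.25 with a 5% mitochondrial limit, -0.73 by the gate), PIK3R1 (-1.49 [-2.08, -0.91], -0.86 by the gate) and the phosphatase DUSP2 (-1.37 [-1.88, -0.88], -0.20 by the gate) were also lower. Interferon-stimulated genes had a median of 0.59 [0.29, 1.01] (0.24 with doublets kept), with OAS1 at 2.04 [0.27, 4.45] on 18 against 3 UMIs (1.45 at Leiden resolution 2). NF-kB targets had 0.56 [0.24, 0.83], with BCL3 at 1.87 [0.59, 3.42] (0.81 by the gate), and interferon gamma-induced genes 0.29. Of the cytotoxic genes GZMK was higher (1.95 [1.46, 2.46], 1.32 with a 5% mitochondrial limit, 0.84 by the gate), while GZMB (-0.99 [-1.56, -0.42]) was at -0.36 with doublets kept and 0.52 by the gate and PRF1 (-0.85 [-1.27, -0.44]) at 0.26 by the gate. The list's median, 0.18, was -0.28 with a 5% mitochondrial limit and 0.65 by the gate. The RNA-quality list had a median of -0.42, and -0.25 by the gate, and its member MALAT1, a nuclear RNA, was at -0.12 [-0.16, -0.08] and 0.02 by the gate.

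Monocyte-like cells of SA had lower interferon-stimulated genes (median -1.10, 18 of 22 lower, from -0.68 without the richest 10% to -1.39 thinned), interferon gamma-induced genes (-0.97, 10 of 15 lower, and -0.73 without the richest 10%) and inflammatory genes (-0.48, and -0.23 thinned). IL6 was at -4.17 [-6.53, -2.48] on 3 against 29 UMIs, CCL7 at -2.10 [-2.20, -1.99], CXCL1 at -1.69 [-1.83, -1.56] and IL1B at -0.93 [-1.03, -0.83], while CCL5 was at 2.23 [2.00, 2.46]. Metallothioneins were higher (0.88, and 1.63 without the richest 10%). Cytotoxic genes, at a median of 2.15, and naive T cell genes, at 1.17, were also higher in these cells. Over the 4 libraries together, 34.9% of monocyte-like cells held a CD3E UMI. KCNMA1, a potassium channel, was at 4.34 [2.76, 6.64] (113 against 3 UMIs) and TIMP3 at 4.78 [2.89, 7.84] (102 against 2, and at least 3.30, on 54 against 0, without its top cells), while CXCL10 was at -5.96 [-7.04, -5.07] (10 against 336, most UMIs of either library in 1 cell, and -5.66 without these cells) and MMP1 rested on 1 cell. In B-like cells of SA, interferon gamma-induced genes were lower in 9 of 12 members, with a median of -1.14 [-1.25, -1.0], WARS at -2.08 [-2.46, -1.73] and GBP1 at -1.83 [-2.34, -1.35]. FCRL3, an inhibitory receptor, was at 1.31 [0.95, 1.68], SIGIRR at 1.25 [0.66, 1.88] and DIPK1B at -2.05 [-2.96, -1.23]. The Fc epsilon and IgE list of B-like cells had medians of -0.17, 0.02, 0.11 and 0.34 in the 4 contrasts, with FCER2, the low-affinity IgE receptor, at 0.30 [-0.25, 0.86] here.

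SA against HC with tropomyosin asks how the donor groups differed under the allergen. The cytotoxic list was higher in CD8 T-like cells of SA by a median of 1.5 [1.38, 1.62], in 11 of 12 members, and by 1.23 (TMM) to 2.17 (without the richest 10%). FASLG, a death ligand, was at 2.31 [1.59, 3.10] (3.04 with a 5% mitochondrial limit), KLRD1 at 1.90 [1.52, 2.28] and NKG7 at 1.89 [1.80, 1.98], with the GZMH-led sub-cluster at 43.7% of SA and 17.5% of HC cells. SCGB3A1 was at -4.05 [-5.96, -2.64] and ADTRP at -3.75 [-5.67, -2.33]. Interferon-stimulated genes were lower in SA in gamma delta T-like cells (-1.06 [-1.23, -0.58], 12 of 19 lower, from -0.41 by the gate to -1.29 thinned), with MX2 at -2.10 [-3.85, -0.69] (-0.66 by the gate). They were also lower in monocyte-like cells (-0.85, 16 of 22 lower, -1.23 without the richest 10%, -0.73 thinned), with MX1 at -1.62 [-1.88, -1.36], in NK-like cells (-0.61 [-0.89, -0.45], 12 of 21 lower, -0.39 without the richest 10%) and in B-like cells (-0.52, and -0.25 without the richest 10%). In CD8 T-like cells the median went the other way, at 0.40 [0.26, 0.54], with 10 of 22 members higher and 2 lower, and at 0.14 with TMM. In CD4 T-like cells the median was -0.49, or -0.69 with TMM and -0.21 without the richest 10%, with IFIT3 at -1.17 [-1.71, -0.66] and IFIT2 at -0.91 [-1.42, -0.43]. The sub-cluster led by IFIT3 held 20 of 1432 of these cells in SA and 111 of 1952 in HC. Without that sub-cluster the median and IFIT2 were no longer lower in SA, with the limit that the listed genes helped to draw it.

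In gamma delta T-like cells, S100B had 36 UMIs in SA and 0 in HC, at least 13.4-fold higher (a log2 ratio of at least 3.33 by the gate, and of 5.60 with doublets kept). DIP2A (2.19 [1.22, 3.29], 1.60 by the gate), the kinase CAMK4 (1.90 [1.10, 2.78], 0.92 with doublets kept, 0.21 by the gate), LDLRAD4, a TGF-beta inhibitor (1.88 [0.99, 2.85]), DEGS1 (1.87 [0.86, 2.99], 0.68 by the gate) and EPHA4 (1.79 [0.73, 2.98], 0.79 by the gate) were also higher. The heat shock genes DNAJB1 (-1.98 [-3.13, -0.97], -0.82 by the gate) and HSPA1A (-1.69 [-2.48, -0.96], -0.46 by the gate) were lower, with ATG5 (-1.89 [-3.21, -0.74], 0.14 by the gate), ARRDC3 (-1.84 [-3.01, -0.82], -1.0 by the gate) and PLEK (-1.76 [-2.60, -0.99], 0.37 by the gate). Outside this class, the unnamed T cell sub-cluster led by HSPA1B and DNAJB1 held 75, 189, 2 and 2 cells (1.72%, 3.61%, 0.039% and 0.054% of cells), and another, led by HSPA6 and HSPA1A, held 81, 46, 46 and 45 (1.85%, 0.88%, 0.89% and 1.22%). GZMK was at 1.17 [0.81, 1.53], FASLG at 1.84 [0.32, 3.64] (1.13 by the gate), PRF1 at -0.91 [-1.34, -0.49] (-0.01 by the gate) and GNLY at -0.96 [-1.12, -0.80] (0.22 by the gate, -1.64 without its top cell). Their list's median was -0.12, and 0.55 by the gate. Interferon gamma-induced genes were lower in 6 of 10 members (-0.61, -0.20 by the gate), with GBP5 at -1.27 [-1.94, -0.64], and NF-kB targets had a median of -0.06. The RNA-quality list was at -0.39 there and at -0.20 in CD4 T-like cells (-0.40 with TMM).

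In monocyte-like cells of SA with tropomyosin, IL6 was at -4.02 [-4.67, -3.43] (-5.06 without its top cells), CXCL5 at -2.31 [-2.41, -2.21] and IL1B at -1.15 [-1.21, -1.09], with the inflammatory list at -0.70. TNF was at 1.14 [0.81, 1.48], and at 0.59 without its top cell, and NF-kB targets at a median of 0.46, with TRAF1 at 0.96 [0.63, 1.29]. Metallothioneins were lower in 7 of 7 members, with MT1M at -5.45 [-6.92, -4.31]. In the other classes PLAU (3.12 [2.00, 4.49], 3.74 without its top cells) and GZMK (2.66 [1.82, 3.62], 3.25 with a 5% mitochondrial limit) were higher in NK-like cells, FCRL3 (1.36 [0.98, 1.74]) and SEMA4B (1.08 [0.52, 1.64]) in B-like cells, and ADGRE1 was lower in CD4 T-like cells (-2.29 [-3.09, -1.56]).

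For the regulatory cytokines of the series title, TGFB1, which makes T cells tolerant, was well measured in gamma delta T-like cells. It stood at 380 [310, 461], 270 [221, 327], 638 [562, 722] and 580 [503, 666] CPM. It was higher in SA than in HC by 0.75 [0.41, 1.09] without and 1.10 [0.76, 1.46] with tropomyosin. With tropomyosin it was lower in HC (-0.49 [-0.90, -0.09], and -0.08 by the delta V gate) and not detectably different in SA (-0.14 [-0.41, 0.14]). CD8 T-like cells had it higher in SA by 0.40 [0.27, 0.53] and 0.73 [0.60, 0.87]. NK-like cells, which had the most, at 1268, 1068, 1406 and 1470 CPM, had 0.15 [0.03, 0.27] and 0.46 [0.33, 0.59], and monocyte-like cells 0.26 [0.08, 0.45] and -0.09 [-0.28, 0.10]. CD4 T-like (-0.02 and 0.10) and B-like cells (0.03 and -0.05) had intervals that held 0. IL10, IL4, IL5, IL13, IFNG, IL17A and AREG had 0 UMIs in gamma delta T-like cells of the 4 libraries. The upper 95% limits for these zeros are 4.06%, 2.56%, 2.70% and 3.62% of cells with a UMI at the depths above, or 13.6, 9.49, 9.34 and 10.6 CPM. TNF was found in 3.37%, 2.82%, 2.96% and 9.0% of them, or 1.18%, 2.31%, 2.34% and 6.06% at 2000 UMIs per cell, against 1.98%, 0.781%, 2.78% and 0.881% of B-like cells.

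**Figure D4:**
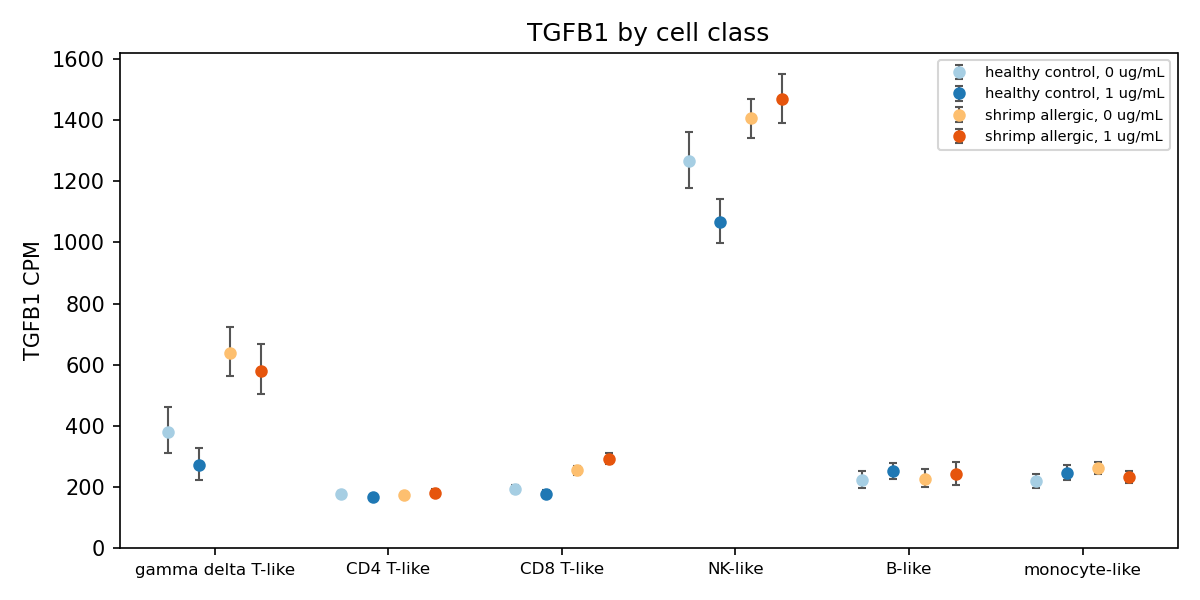
TGFB1 level (CPM) by class in the 4 libraries, with exact Poisson 95% intervals. In gamma delta T-like cells both SA libraries (638 and 580 CPM) lie above both HC libraries (380 and 270 CPM).

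The responses of the donor groups to tropomyosin were also set side by side. Over genes with enough counts in both, the Pearson correlation of the HC and SA log2 ratios was 0.27 in monocyte-like cells (6572 genes). It was -0.02 in gamma delta T-like cells (1808 genes), -0.08 in CD4 T-like, -0.06 in CD8 T-like, -0.12 in NK-like and -0.05 in B-like cells. These correlations are across genes, which are not independent replicates. In gamma delta T-like cells the standard deviation of the ratios was 0.32 in HC and 0.30 in SA. Counting error in both ratios weakens such correlations, and how much of the spread it makes up was not computed. Low values therefore do not show that the responses were unrelated. The interferon-stimulated list differed most in gamma delta T-like cells, at 1.26 in HC and -0.14 in SA, a difference that was not tested.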

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

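Tests chosen only after their result was seen were the sub-cluster test in CD4 T-like cells, the comparison with random lists and the mix of CD8 sub-clusters. The mix was first tested on the sub-clusters used elsewhere (highest median 0.31), which was void because the listed genes helped to draw them. It was redone on sub-clusters drawn without these genes, though genes that go with them were kept. The sub-cluster test in CD4 T-like cells was void for the same reason and was not redone.

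The results in this paragraph and the next 3 are lists or genes higher with tropomyosin in 1 donor group and lower in the other. Each had a counting interval without 0 in both groups. Lists also needed a percentile outside the middle 95% of random lists in both. Percentiles as low as 0.31 also came up for simulated lists with no change, and 4 lists had a lowest percentile no lower than that: the Treg program (0.83, SA) and metallothioneins (0.36, SA) in NK-like cells, checkpoint genes in monocyte-like cells (1.5, SA) and interferon gamma-induced genes in B-like cells (0.53, HC). The difference between the groups was not tested, and each group is 1 pair of libraries. Metallothioneins, the zinc-binding proteins, went apart most in monocyte-like cells: the median was 0.79 in HC and -2.04 in SA, a difference (SA minus HC) of -2.82. MT1M was at 1.70 and -4.63 (difference -6.34), MT1G at 0.70 and -2.92 (-3.62, and -4.17 in SA without its top cell), MT1H at 0.66 and -2.65 (-3.31, and -3.93 in SA without its top cell), MT1E at 1.38 and -1.54 (-2.92), MT1F at 0.79 and -2.04 (-2.82) and MT2A at 1.29 and -1.52 (-2.81). In NK-like cells the list was at 1.58 in HC and -0.73 in SA (-2.31), and leaving out the cells richest in it was not run there.

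Monocyte-like cells also went apart in transcripts of other cells. Cytotoxic effectors were at 0.95 in HC (0.24 over members with at least 50 UMIs) and -0.75 in SA, a difference of -1.69. GNLY was at 1.51 and -0.84 (-2.35), CTSW at 1.41 and -0.71 (-2.12), KLRD1 at 1.41 and -0.83 (-2.24) and NKG7 at 0.95 and -0.98 (-1.93). Checkpoint genes were at 1.41 and -0.80 (-2.21). Genes that mark monocytes themselves were at 0.29 and -0.30 (-0.59), with the calprotectin subunits S100A8 at 0.80 and -0.49 (-1.29) and S100A9 at 0.34 and -0.80 (-1.14).

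In NK-like cells the heat shock list was at 0.24 in HC and -0.46 in SA, a difference of -0.70, but its HC median was -0.033 with a 5% mitochondrial limit and -0.0069 at Leiden resolution 2, so it did not keep the direction on which the contrast rests. At resolution 2 the class held 284 cells and 727466 UMIs in HC with tropomyosin, against 285 and 782604. HSPA6 was at 2.02 and -1.17 (-3.19), HSPE1 at 1.27 and -0.61 (-1.88) and HSPD1 at 1.25 and -0.92 (-2.17). In each of these 1 cell held much of the RNA. It had 84.8% of the HSPA6 UMIs of SA without tropomyosin, and HSPA6 in SA was at 1.24 without the top cells and -0.066 with doublets kept. In HC with tropomyosin 1 cell had 57.6% of the HSPD1 and 50% of the HSPE1 UMIs, and these genes were at 0.40 and 0.59 without the top cells, and at -0.0045 and 0.37 with a 5% mitochondrial limit. Hypoxia and glycolysis genes were at 0.22 (0.093 at resolution 2) and -0.21 (-0.43), with PKM, a glycolytic enzyme, at 0.31 and -0.34 (-0.65). The Treg program was at 0.62 (0.55 at resolution 2) and -0.35 (-0.98), and in SA at 0.13 when members with 1 UMI were let in. TNFRSF4, a costimulatory receptor, was at 1.67 and -1.45 (-3.12). IL2RA, the high-affinity IL-2 receptor chain, was at 0.98 (0.51 at resolution 2) and -3.04 (-4.02). In HC with tropomyosin 1 NK-like cell held 1933 UMIs of IL2, and in SA without it 1 cell held 385 of IL3, both T cell products. Whether such cells set the values of TNFRSF4, IL2RA and the Treg list was not tested.

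In B-like cells interferon gamma-induced genes were at -0.17 in HC and 0.32 in SA, a difference of 0.49, but the HC median was -0.053 without the richest 10% of cells and 0.050 with cells thinned. The guanylate-binding proteins GBP1 (-0.31 and 1.17, difference 1.48), GBP2 (-0.29 and 0.68, 0.97), GBP4 (-0.42 and 0.48, 0.90) and GBP5 (-0.38 and 0.67, 1.05) are members that went the same ways. CEBPD in CD4 T-like cells was at 0.94 and -1.45 (-2.39), and TMOD2 in CD8 T-like cells at -1.01 and 0.62 (1.63).

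The first pattern weighed is that interferon-stimulated genes were higher in the tropomyosin libraries. Gamma delta T-like (-0.14) and B-like cells (0.06) of SA did not show it and are not among the medians weighed. Of the 10 medians of at least 0.25, 9 stayed at or above 0.12 without the richest 10% of cells. This argues against a few cells as the whole cause. With cells thinned 10 did so, but thinning leaves the expected share of a gene within each cell unchanged. It checks the weight of deep cells only, so depth per cell stays open otherwise. All 10 lay above the middle 95% of random lists, but they had been picked for their size. The median ratio over all measured genes lay between -0.10 and 0.07 in the tropomyosin contrasts. That argues against a shift of all genes as the whole cause. In CD4 T-like cells of HC the median was 0.0495 without the sub-cluster led by IFIT3, a void test, so whether few cells carry the difference there stays open. A difference between wells or libraries other than tropomyosin cannot be told apart from it, because the series holds 0 other libraries of the same donor group and dose. An effect of tropomyosin stays open as well, untested.

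The second pattern is that cytotoxic effectors were higher in CD8 T-like cells of SA. Stray NK-like cells are argued against, because genes chosen to mark NK cells, 4 of them with enough counts, had medians of 0.38 and -0.50, at least 1.15 below the cytotoxic list. Another mix of CD8 sub-clusters is a candidate explanation. Within sub-clusters drawn without the listed genes the highest median was 0.35 [-0.31, 0.84], on only 4 members with low counts. The sub-cluster with 12 measured members had 0.21 [0.09, 0.37] without and -0.0035 [-0.11, 0.16] with tropomyosin. Genes that go with the listed ones were kept in the clustering, so low medians may partly have been set in advance. The test therefore does not decide for this mix. Whether that mix goes with allergy or with the donors cannot be told apart, as the series holds 0 other libraries of either donor group and dose.

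The third pattern is that TGFB1 was higher in gamma delta T-like cells of SA. Without tropomyosin only 1 of the 5 other classes, CD8 T-like cells (0.40), had it higher by at least 0.3, and with it CD8 T-like (0.73) and NK-like cells (0.46) did. That count depends on the cut. Without tropomyosin NK-like (0.15 [0.03, 0.27]) and monocyte-like cells (0.26 [0.08, 0.45]) also had intervals above 0. Thinned, CD8 T-like cells had 0.27, NK-like 0.31 and monocyte-like 0.36 [-0.20, 0.94]. The intervals of CD4 T-like (-0.02 and 0.10) and B-like cells (0.03 and -0.05) held 0 in both comparisons. This argues against a shift in every class, but the difference was not particular to gamma delta T-like cells. In gamma delta T-like cells the smaller log2 ratio of both comparisons was 0.79 without the richest 10% of cells, which argues against a few cells. It was 0.77 with cells thinned. Thinning leaves the expected share of TGFB1 within each cell unchanged, so this checks the weight of deep cells only and cannot decide on depth otherwise. A difference between the donors, or between wells, was not tested and stays open, as does allergy. The pattern is a hypothesis, found and tested in the same 4 libraries.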

How the results depend on the processing

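Alternatives chosen after the data were seen were leaving out the richest 10% of cells, thinning cells for list medians, leaving out a gene's top cell, the delta V gate for expression and leaving out sub-clusters; the rest were planned. No paired analysis was possible because the labels do not say which libraries share a donor. Below, values in sequence are HC without, HC with, SA without and SA with tropomyosin unless named.

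Of 240 shares under an alternative, 173 stayed within their 95% binomial interval and 67 did not. At resolution 0.5, B-like cells (joined to switched B cells) were 13.6%, 14.7%, 9.0% and 8.39%, CD4 T-like 40.1%, 38.6%, 40.8% and 40.7%, MAIT-like 4.76%, 5.02%, 4.91% and 4.81%, and CD8 T-like in SA 25.8% and 28.5%; gamma delta T-like cells had no cluster of their own, so no value. At resolution 2, CD4 T-like cells were 35.2% (HC without) and 36.6% and 36.4% (SA). At most 5% mitochondrial UMIs gave B-like 6.63%, 7.72% and, in SA without, 6.07%, CD4 T-like 40.3%, 40.7%, 41.2% and 42.0%, CD8 T-like in SA 22.9% and 24.7%, and MAIT-like in HC 2.00% and 1.54%. With each library clustered on its own, B-like cells were 13.8% in HC without, CD4 T-like 31.5% in HC with and 41.2% in SA without, CD8 T-like 19.8%, 24.5% and, in SA without, 25.8%, and MAIT-like 4.94% in SA with tropomyosin.

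The gate on TRDC without alpha or beta constant genes gave gamma delta shares of T cells of 0.173%, 0.173%, 0.222% and 0.0335%, and of all cells 0.137%, 0.153%, 0.252% and 0.0815%; thinned, 0.234%, 0.327%, 0.278% and 0.204% of T cells and 0.234%, 0.318%, 0.303% and 0.221% of all cells. It kept too few cells for expression, which was not run. The delta V gate gave 5.37%, 6.34%, 8.54% and 8.25% of T cells and 4.35%, 5.00%, 6.96% and 6.87% of all cells; thinned, 4.34%, 4.91%, 6.85% and 6.65% of T cells and 3.51%, 3.98%, 5.64% and 5.59% of all cells. The gate also takes cells with a delta V UMI outside the gamma delta T-like sub-cluster, among them TRDV1 cells and some CD4 T-like and CD8 T-like cells.

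Of 217 alternative values of the main list medians, 194 stayed within their counting interval, 23 did not, and the cause was not tested. For cytotoxic effectors in CD8 T-like cells, SA against HC, these were 1.39, 1.34 and 2.28 without tropomyosin (TMM, thinned, without the richest 10%) and 1.23, 1.25, 1.30, 1.36 and 2.17 with it (TMM, median-of-ratios, CPM without mitochondrial, ribosomal protein and immunoglobulin genes, thinned, without the richest 10%). For interferon-stimulated genes without the richest 10% they were, in the tropomyosin contrasts, 0.13 (CD4, HC), 0.11 (CD8, HC), 0.21 (CD8, SA), 0.52 (NK, SA), 0.39 (B, HC) and 2.02 (monocyte-like, HC). Without the interferon-led sub-cluster CD4 T-like cells of HC had 0.0495, which says nothing about stability because the listed genes helped to draw that sub-cluster. Thinned monocyte-like cells of SA had 1.80, and the delta V gate gave 0.22 in SA. In SA against HC gamma delta T-like cells had 0.24 with doublets kept (without tropomyosin), and -0.41 by the gate and -1.29 thinned (with it). Thinned inflammatory medians in monocyte-like cells were 1.75 in HC and 1.53 in SA, and interferon gamma-induced genes, SA against HC without tropomyosin, had -0.73 without the richest 10%. TGFB1 in gamma delta T-like cells, SA against HC, stayed in its interval in 16 of 16 alternatives under planned and added settings, while its tropomyosin ratio in HC went from -0.49 to -0.084, out of its interval, by the delta V gate. With a minimum of 20 UMIs, 50 of the 112 named genes were still named, as genes with fewer counts entered the ranking.

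Of 600 values of other medians, 528 were within their interval, 65 moved and 7 reversed; of 3229 values of single genes, 3075, 139 and 15. The cause was not tested for the reversals. By the delta V gate ATG5 was at 0.14, PLEK at 0.37, PSMB9 at 0.030, GZMB at 0.52, PRF1 at 0.26, GNLY at 0.22 and MALAT1 (SA against HC without tropomyosin) at 0.017. With tropomyosin MALAT1 was at -0.015 (TMM), -0.0060 (median-of-ratios) and -0.0084 (CPM without mitochondrial, ribosomal protein and immunoglobulin genes). A 5% mitochondrial limit gave PPBP -0.37, HSPD1 in NK-like cells of HC -0.0045 and the heat shock median there -0.033, which was -0.0069 at resolution 2. Without their top cell HSPA1A in B-like cells of HC was at -0.044 and HSPA6 in NK-like cells of SA at 1.24. Without the interferon-led sub-cluster, IFIT2 in CD4 T-like cells (SA against HC with tropomyosin) was at 0.39 and the interferon-stimulated median at 0.0058, with the same limit. The cytotoxic median of CD8 T-like cells of SA was -0.0047 with TMM and -0.021 with doublets kept, the Treg program of NK-like cells of SA 0.13 with members of 1 UMI let in, and interferon gamma-induced genes of B-like cells of HC 0.050 thinned.

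Depth limits the gamma delta T-like class most. On simulated Poisson counts 50.5% of 2-fold and 89.3% of 4-fold changes in SA cells of this class were recovered.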

Other observations

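Some T and NK clusters met no marker rule. No expression ratio is given for them as classes, though some of their cells enter the delta V gate. Clusters led by TRDV1 with KLRC2, by heat shock genes such as HSPA1A and HSPA6, and by CREM and NR4A2 made up most of them. In the heat shock sub-clusters of 268 and 218 cells, TRDV2 was found in 0.0% of cells of both and TRGV9 in 0.0% and 0.5%. In NK-like cells of HC with tropomyosin, 1933 UMIs of IL2 and 124 of IL21 came from 1 cell. In SA without tropomyosin the same class had 385 UMIs of IL3 in 1 cell. The cytokines IL2, IL3 and IL21 are T cell products, and these values were not taken as differences between groups.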
